A study of Mus musculus with 8 samples.

How the data were processed

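Cytoplasmic RNA was captured on oligo-dT beads and second-strand cDNA was made with dUTP, per the labels' protocols. TopHat, Bowtie2 2.2.4, Cufflinks, Cuffdiff and the build mm9 were named, with no role or order, in the submitters' processing notes. The repeat table gave the read count of each element and its RPKM in each library, per the file headers. It held 15389 LINE, 2455 LTR and 13 satellite elements of at least 5001 bp. The counter and the treatment of reads that map to several elements were not given in the sources used here. The other files gave FPKM of transcripts assembled in each library by the authors, with no gene names. FPKM are not counts, and the loci carry no depth of their own.

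RPKM, by the authors, are reads per kilobase and per unit of library total, so the total was recovered from count and RPKM for each library. Recomputed RPKM lay within 0.011 of the deposited RPKM for 100% of elements in 6 libraries and 99.994% in the others. The 778 elements on random scaffolds had 0 reads, and 1811 elements had 0 reads in all 8 libraries.

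Before the data were examined, the test of repeats was set as limma on log2(RPKM + 0.1), and the gene test, the sets, the rule for named items and most alternatives were set too. Because the repeat table holds counts, edgeR 4.0.16 (quasi-likelihood, R 4.3.3) on counts with the recovered totals became the main test, and limma 3.58.1 and DESeq2 1.42.0 were alternatives. The test of read sums per family was added after the data were seen. Families needed a mean of 1 RPM and elements a mean RPKM of 0.1. Each factor was fitted with the other factors as covariates, leaving 4 residual degrees of freedom, and a fit with 1 interaction left 3. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Other scalings moved all repeats together. TMM moved the median change over elements by log2 0.44 for DAXX, −0.14 for DNMT and 0.23 for the medium, and by −0.25 for DAXX in J1, 1.14 for DAXX in TKO and 1.41 for their difference. LINE1 elements were 9625 of the 11322 tested, so TMM, median scaling and LINE1 scaling each set the typical LINE1 element near 0. The repeat counts alone do not say which scaling holds.

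Sets of at least 5 elements were tested with limma's camera at a preset correlation of 0.01. The LINE and LTR types of the table served as the planned classes. Class names such as IAP and MERVL had also been written down beforehand, for a table without types, and their test beside the types was added after the data were seen. Loci were matched where they overlapped reciprocally by at least 50% with 1 locus in each library (GenomicRanges 1.54.1). This gave 9719 loci out of 56568 groups of loci, and 9658 had a mean FPKM of at least 1. A locus not assembled, or assembled with other bounds, in any 1 library was left out. Limma was run on log2(FPKM + 1), so folds of low loci are understated. Matched positions span the loci of the 8 libraries. The files do not state whether positions count from 0 or 1.

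The rule for named items took up to 10 each way with an adjusted p under 0.05 and the same sign in 4 of 4 pairs, named by largest change with the rest counted. At most 2 loci each way are printed, since the files pair no names with them. Families named beyond the called ones were chosen after their values were seen. Gene lists, the levels of Daxx and the Dnmt genes and the choice among entries of a gene were not analysed here, because the annotation at hand is of another build.

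The tests were run on simulated data with known changes. For DAXX, 69 of 100 elements changed 4-fold and 8 of 100 changed 2-fold were recovered among 11322, as were 4 of 5 and 1 of 5 families among 44, and 91 of 100 and 51 of 100 loci among 9658. For the DAXX by DNMT interaction, 0 of 100 elements and 0 of 100 loci at either fold were recovered, and 1 of 5 families at 4-fold. The simulated elements, families and loci varied independently, with no effect of the other factors. In the data the estimated correlation was 0.854 among LINE and 0.468 among LTR elements, so the recovered shares do not carry over to these data. Alternatives covered pseudocounts, filters, scalings, tools, covariates and the omission of each library. Python 3.11.15 and pandas 2.3.3 read the files.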

Results

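The data were RNA-sequencing libraries of mouse embryonic stem cells in 8 groups of 1 library each. Cells of the J1 line and of TKO, a line with 3 DNA methyltransferases knocked out, had DAXX intact or knocked out. DAXX is a histone chaperone that acts together with ATRX. Each of the 4 lines was grown in regular medium or for 72 hours with 2i and vitamin C, which the labels call the ground state. The 2i were the MEK inhibitor PD0325901 at 1 µM and the GSK3b inhibitor CHIR99021 at 3 µM, and vitamin C was at 100 µg/ml. The libraries are named here by line and medium, with "2i" for 2i plus vitamin C. No group had a replicate, so each factor was examined over the 4 pairs of libraries that differ in that factor alone. In the fits without interaction the p-values rest on the residual over all 8 libraries. It holds the spread between those pairs, and so interactions as well as noise. It also holds the interaction of the other 2 factors, which cancels within each pair. So the p-values for the medium are not those of a test paired by line. Both edgeR and limma draw the spread in part from other families, elements or loci. For DAXX and DNMT the pairs come from 4 lines, each in both media, so pairs of the same lines are not independent. The fits hold no term for the line, so these p-values do not measure the spread between lines of a genotype. The fits within J1 and within TKO draw their spread from both backgrounds.

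Library totals recovered from the repeat table ranged from 67.4 M reads in J1 2i to 99.1 M reads in TKO regular, and RPM are reads per M of that total. Reads in the 17857 listed repeat elements made up 8.28% of the total in TKO DAXX-knockout 2i and 19.3% in TKO regular. The elements fall into 65 families, of which 44 were tested. A floor of 3 reads corresponded to between 0.0303 and 0.0445 RPM, and covers counting error only. The assembled transcripts carried no gene names, so the knocked-out genes were not examined and the labels were taken as given.

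**Figure D1:**
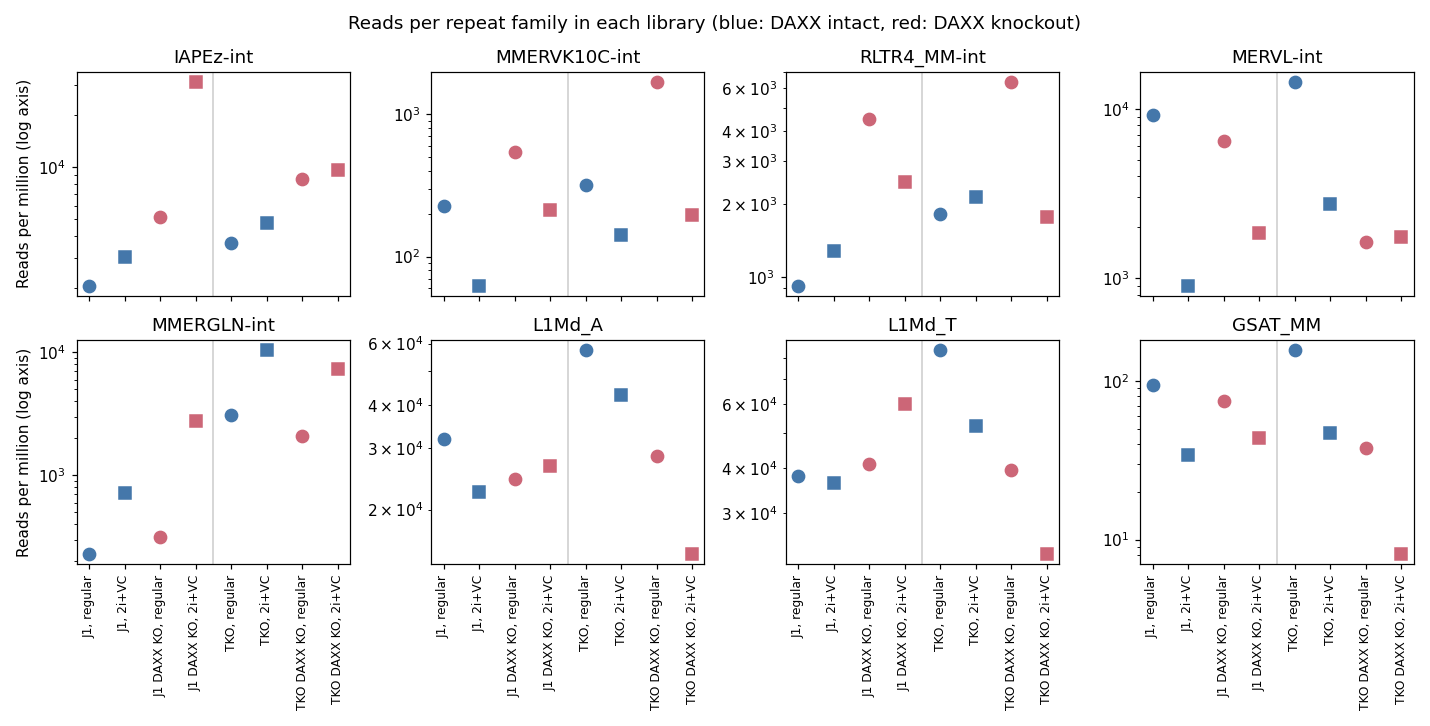
RPM (log axis) of 8 repeat families in each of the 8 libraries, with blue for DAXX intact, red for DAXX knockout, circles for regular medium and squares for 2i plus vitamin C. Each point is 1 library; IAPEz-int was at 31233 RPM in J1 DAXX-knockout 2i and between 2061 and 9704 RPM in the others.

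The comparison of DAXX-knockout with DAXX-intact lines asks which repeats differ when DAXX is lost. IAPEz-int, the internal part of intracisternal A-particle retroviruses, had 2.49 times as many RPM in the knockout in J1 regular and 10.3 times as many in J1 2i, and the ratios in TKO were 2.36 and 2.04. MMERVK10C-int, another family of the ERVK type, had ratios of 2.43 and 3.42 in J1 and 5.29 and 1.39 in TKO. RLTR4_MM-int, of the ERV1 type, had ratios of 4.85 and 1.94 in J1 and 3.49 and 0.824 in TKO. Its top 10 elements held 35.9% of its reads in J1 regular and 62.3% in J1 DAXX-knockout regular. In that pair its median element changed by log2 0.89, beside 2.28 for the family. Among the LINE1 families, L1Md_A was lower in 3 of 4 pairs and L1Md_T in 2 of 4.

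No family passed the threshold in edgeR's test of family sums, with 3 at an unadjusted p under 0.05 and 1, MMERVK10C-int, called by DESeq2. With TMM, median scaling or LINE1 scaling, edgeR called 1 family in each case, IAPEz-int. IAPEz-int had a fitted fold of 3.59 with an adjusted p of 0.0576 in edgeR, and its log2 ratios were 1.74 ± 1.09 (SD of 4 pairs), above 0 in 4 of 4. MMERVK10C-int had a fitted fold of 2.90 with the same adjusted p, and log2 ratios of 1.48 ± 0.82, above 0 in 4 of 4. Over the 13 alternatives, in edgeR, limma and DESeq2, the adjusted p of IAPEz-int ranged from 0.00606 to 0.485 and was past the threshold in 7, and that of MMERVK10C-int from 5.36e-05 to 0.278, past it in 4. The log2 change of IAPEz-int was 1.84, and 1.17 without J1 DAXX-knockout 2i. RLTR4_MM-int had a fitted fold of 2.32 and an adjusted p of 0.230 in edgeR, and was called without TKO DAXX-knockout 2i. L1Md_A and L1Md_T had fitted folds of 0.640 and 0.794 with adjusted p of 0.646 and 0.664. The log2 change of L1Md_T was −0.33 as deposited, −0.14 under TMM and −0.010 under median scaling. Without J1 DAXX-knockout 2i 3 families were called, 2 higher and 1 lower. Without TKO DAXX-knockout 2i 3 were called, without J1 DAXX-knockout regular 2 and without TKO regular 1, all higher.

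Of 11322 single elements, edgeR called 759 higher and 7 lower with DAXX knockout. They included 703 of 804 IAPEz-int, 38 of 75 MMERVK10C-int and 15 of 45 RLTR4_MM-int elements. Copies of a family are near-identical and the treatment of reads that map to several copies was not stated, so the elements are not independent. The element with the largest rise was an IAPEz-int copy on mm9 chromosome 4 from 116865082 to 116871463, with a fitted fold of 7.19 and an adjusted p of 0.00698 in edgeR. It was at 27.7 RPKM in J1 DAXX-knockout 2i and at most 3.92 in the others. Its log2 change of 2.85 was 1.85 without J1 DAXX-knockout 2i, 2.18 without J1 2i and 3.49 without TKO DAXX-knockout 2i. Its call was lost without J1 regular, J1 2i, J1 DAXX-knockout regular or TKO DAXX-knockout regular. The count of 766 fell to 0 without J1 regular, 0 without J1 DAXX-knockout regular, 1 without TKO DAXX-knockout regular, 2 without J1 2i, both lower, and 18 without TKO 2i. Without J1 DAXX-knockout 2i it was 4252, of which 824 were higher and 3428 lower.

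**Figure D2:**
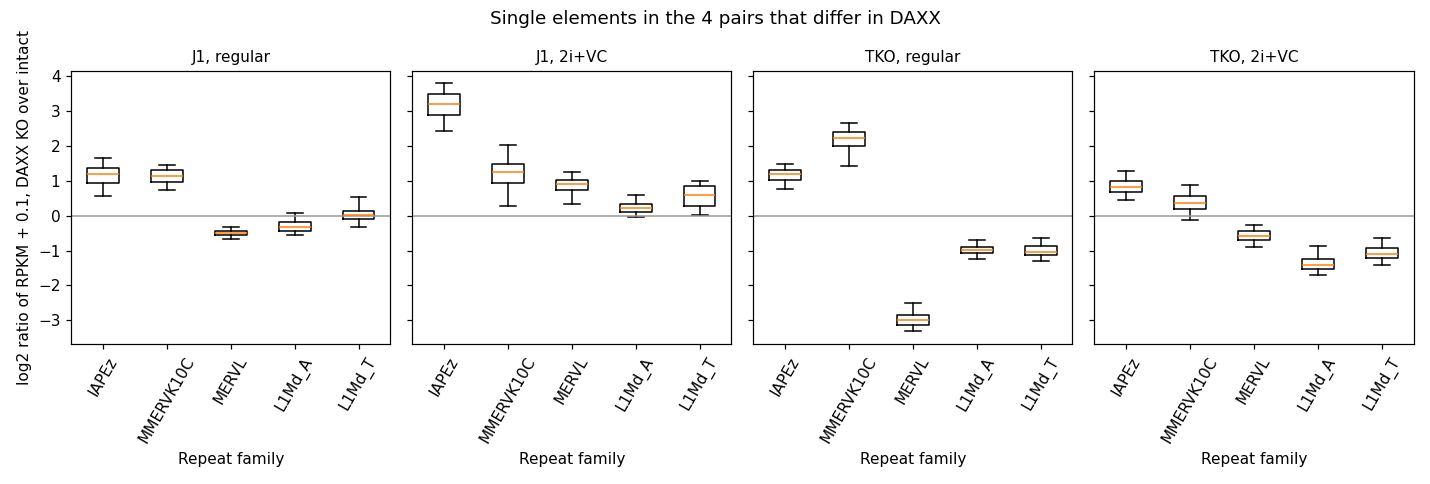
Log2 ratio of RPKM + 0.1 of DAXX-knockout over DAXX-intact libraries for the elements of 5 families in each of the 4 pairs. Boxes are quartiles with a line at the median and whiskers at the 5th and 95th percentile of elements, which are not replicates; the median IAPEz-int element was at 1.19 in J1 regular and 3.21 in J1 2i.

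As sets, LTR elements were placed higher and LINE elements lower with DAXX knockout by limma's camera with a preset correlation. Camera compares a set with the other elements. The 9625 LINE and 1696 LTR elements were nearly all of the 11322, so these placements mirror each other and are 1 result. With an estimated correlation the adjusted p was 0.0720 for LTR and 0.0832 for LINE. Limma's fry, which tests whether a set moves on its own, gave an adjusted p of 0.298 for each type. When LTR elements were divided by family name, IAP elements were placed higher than other elements by camera. The adjusted p was 0.0108 with an estimated correlation, while fry gave 0.115. The adjusted p with an estimated correlation was 0.112 for ERV1, other ERVK and LINE1 elements and 0.393 for MERVL elements.

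The series asks what DAXX does with and without DNA methylation, so its effect was also fitted within each background. In TKO, GSAT_MM, the major satellite, fell to 0.208 of its level with DAXX knockout, with an adjusted p of 0.0284 in edgeR and ratios of 0.240 in regular medium and 0.172 in 2i. Of the 12 listed GSAT_MM elements 1 lies off the random scaffolds and held all the reads. LINE1 elements together were at 149042 RPM in TKO regular and 100179 in TKO 2i, at 71687 and 40717 with DAXX knockout, and between 62308 and 91763 in the 4 J1 libraries. L1Md_A and L1Md_T were at 0.422 and 0.458 of the intact level, with adjusted p of 0.0747 and 0.0764, and MERVL-int at 0.334 with one of 0.117. The ratios of MERVL-int were 0.114 in regular medium and 0.647 in 2i. Its log2 change of −1.58 was −0.57 without TKO DAXX-knockout regular and −3.20 without TKO DAXX-knockout 2i, where it was called, and −0.69, −0.59 and −0.20 under TMM, median scaling and LINE1 scaling. The log2 changes of GSAT_MM, L1Md_A and L1Md_T were −2.26, −1.25 and −1.13 as deposited, −1.46, −0.45 and −0.30 under TMM and −1.40, −0.38 and −0.24 under median scaling. LINE1 scaling, which sets LINE1 families near 0, gave −1.12 for GSAT_MM. The adjusted p of GSAT_MM was 0.0618 under TMM in edgeR and ranged from 2.37e-08 to 0.389 over 13 alternatives, of which 8 were past the threshold. IAPEz-int had a fitted fold of 5.94 in J1 with an adjusted p of 0.179 in edgeR and of 2.23 in TKO with one of 0.141. In J1 its log2 change of 2.57 was 1.22 without J1 DAXX-knockout 2i and 3.45 without J1 DAXX-knockout regular. It was called without J1 DAXX-knockout regular, TKO DAXX-knockout regular or TKO DAXX-knockout 2i, and its adjusted p ranged from 0.000325 to 0.919 over 13 alternatives in edgeR, limma and DESeq2. In TKO its log2 change of 1.16 was 0.60 without TKO DAXX-knockout regular, and 1.98, 2.03 and 2.31 under TMM, median scaling and LINE1 scaling, and it passed in 4 of 13 alternatives with adjusted p from 0.0210 to 0.550. MMERVK10C-int had fitted folds of 2.92 in J1 and 2.88 in TKO, with adjusted p of 0.329 and 0.0747 in edgeR. It passed in 3 of 13 alternatives in J1 and 5 of 13 in TKO, where its log2 change of 1.53 was 0.61 without TKO DAXX-knockout regular, 2.25 without TKO DAXX-knockout 2i, and 2.26, 2.32 and 2.58 under TMM, median scaling and LINE1 scaling.

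GSAT_MM was the family called in TKO in edgeR, with 24 at an unadjusted p under 0.05, and it was lower. DESeq2 called 1 family higher and 24 lower, LINE1 scaling 8 higher and 1 lower, median scaling 0 and 1 and TMM 0. The count was 0 without J1 regular, J1 2i, TKO regular or TKO 2i. It was 2 higher and 22 lower without J1 DAXX-knockout regular or J1 DAXX-knockout 2i, 0 and 10 without TKO DAXX-knockout regular and 3 and 5 without TKO DAXX-knockout 2i. In J1 edgeR called 0 families, with 4 at an unadjusted p under 0.05 and 1 called by DESeq2, and 2 or 3 without J1 DAXX-knockout regular, TKO DAXX-knockout regular or TKO DAXX-knockout 2i.

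The difference between the backgrounds was tested itself. No family was called in edgeR, with 19 at an unadjusted p under 0.05 and 23 called by DESeq2. GSAT_MM had a fitted difference of log2 −2.32, MMERGLN-int of −1.82 and L1Md_T of −1.59, each with an adjusted p of 0.110 in edgeR. In the same order these were −1.08, −0.53 and −0.32 under TMM, −1.22, −0.67 and −0.46 under median scaling and −0.90, −0.31 and −0.13 under LINE1 scaling. For IAPEz-int the difference was −1.41 with an adjusted p of 0.229 in edgeR, −0.068 under TMM, −0.21 under median scaling, 0.14 under LINE1 scaling, −0.087 without J1 DAXX-knockout 2i and −2.32 without J1 DAXX-knockout regular, where it was called. Without J1 DAXX-knockout 2i that of MMERGLN-int was −1.04 and that of L1Md_T −0.99, and without J1 DAXX-knockout regular that of MMERGLN-int was −2.43. Without J1 DAXX-knockout regular 24 families were called, without TKO DAXX-knockout regular 12 and without TKO DAXX-knockout 2i 6.

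Within TKO, 6392 elements were called lower and 387 higher, among them 3003 of 4951 L1Md_T, 2188 of 3065 L1Md_A and 463 of 575 MERVL-int elements lower and 315 of 804 IAPEz-int and 65 of 75 MMERVK10C-int elements higher. With other scalings the direction turned, with 805 higher and 12 lower under TMM, 847 and 22 under median scaling and 923 and 11 under LINE1 scaling. At a mean RPKM of at least 1 there were 0 higher and 2 lower, and with no filter 62 and 1493. The count of 6779 was 3 without TKO regular, 14 without TKO 2i, 18 without J1 regular, 24 without J1 2i, 886 without TKO DAXX-knockout 2i, of which 268 were higher, and 1897 without TKO DAXX-knockout regular. Within J1, 884 elements were called higher and 2 lower, 797 of the former IAPEz-int. That count of 886 was 0 without J1 2i, 11 without J1 regular, 266 without J1 DAXX-knockout 2i and 2997 without J1 DAXX-knockout regular.

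The comparison of TKO with J1 lines asks which repeats differ where the DNA methyltransferases are absent. MMERGLN-int, a retrovirus family of the ERV1 type, rose with a fitted fold of 7.48 and an adjusted p of 0.00133 in edgeR, with ratios from 2.66 to 14.5 in the 4 pairs. IAPEy-int rose with a fitted fold of 5.98 and an adjusted p of 0.000697, with ratios from 4.30 to 8.63. MuRRS-int, IAPLTR3-int and ETnERV3-int rose with fitted folds of 3.20, 2.52 and 2.75 and adjusted p of 0.0337, 0.0337 and 0.0341. All 5 were higher in 4 of 4 pairs, with log2 ratios of 2.94 ± 1.14 for MMERGLN-int and 2.62 ± 0.51 for IAPEy-int (SD of 4 pairs). Several rest on few elements. Off the random scaffolds lie 16 of the 143 IAPEy-int elements, and 6 of MuRRS-int, 23 of IAPLTR3-int and 11 of ETnERV3-int. IAPLTR3-int was at 1.81 to 8.51 RPM and ETnERV3-int at 3.87 to 18.8 RPM. IAPEz-int had a fitted fold of 1.05 and an adjusted p of 0.970 in edgeR. It was higher in 3 of 4 pairs, with ratios of 1.76 and 1.57 with DAXX intact, 1.67 in DAXX-knockout regular and 0.311 in DAXX-knockout 2i.

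MMERGLN-int and IAPEy-int passed the threshold under each of 13 alternatives, with highest adjusted p of 0.0454 and 0.0184, and MuRRS-int, IAPLTR3-int and ETnERV3-int under 8, 6 and 5. With other scalings the split of 5 higher and 0 lower was 2 and 2 under TMM, 4 and 2 under median scaling and 3 and 0 under LINE1 scaling. The count of 5 was 2 without J1 DAXX-knockout regular and 3 without J1 regular, J1 2i, TKO regular or TKO 2i. MuRRS-int lost its call without J1 DAXX-knockout regular or TKO 2i. IAPLTR3-int lost it without J1 regular, J1 2i, J1 DAXX-knockout regular, TKO regular or TKO 2i, and ETnERV3-int without the first 4 of these or TKO DAXX-knockout 2i. IAPEy-int was at 0.664 RPM in J1 regular, 1.28 in J1 2i, 0.606 in J1 DAXX-knockout regular and 3.05 in J1 DAXX-knockout 2i. In TKO it was at 3.18 RPM in regular medium and 11.0 in 2i, and with DAXX knockout at 4.85 and 13.1. Of single elements 66 were called higher and 3 lower, with 53 of 56 MMERGLN-int elements among the former. Under TMM 60 were higher and 267 lower, under median scaling 63 and 288 and under LINE1 scaling 62 and 286. The count of 69 was 118 without J1 DAXX-knockout 2i and 45 without J1 DAXX-knockout regular. As sets, the LINE and LTR types, which mirror each other in camera, had an adjusted p of 0.00850 in it. It was 0.783 with an estimated correlation, and 0.745 in fry. ERV1 elements by name were placed higher than other elements by camera with an adjusted p of 0.00748 with an estimated correlation. Fry, which makes no comparison with other elements, gave an adjusted p of 0.0356 for ERV1.

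The comparison of media asks which repeats differ in 2i plus vitamin C. MERVL-int, an ERVL family transcribed in the early cleavage embryo, fell to 0.257 of its level with an adjusted p of 0.0359 in edgeR. Its ratios were 0.0982 in J1, 0.287 in J1 DAXX-knockout, 0.189 in TKO and 1.08 in TKO DAXX-knockout, where it was at 1634 RPM in regular medium against 14387 RPM in TKO. MMERVK10C-int fell to 0.277 of its level, with an adjusted p of 0.00992 and lower in 4 of 4 pairs. MMERGLN-int and IAPEy-int rose with fitted folds of 4.53 and 3.11, the same adjusted p and higher in 4 of 4 pairs. IAPEY3-int, ERVL-B4-int and MERVL_2A-int fell to 0.247, 0.232 and 0.272 of their levels with adjusted p of 0.0123, 0.0184 and 0.0490. The first 2 were lower in 4 of 4 pairs, while MERVL_2A-int was lower in 3 and had a ratio of 1.15 in TKO DAXX-knockout. ERVL-B4-int is 1 element, at 1.60 to 23.5 RPM. Its ratios in J1, J1 DAXX-knockout, TKO and TKO DAXX-knockout were 0.113, 0.254, 0.168 and 0.781. Those of MERVL_2A-int were 0.0969, 0.3075, 0.205 and 1.15 in the same order. Both lie near those of MERVL-int, so these may not be separate results. MERVL-int passed the threshold under 4 of 13 alternatives, MERVL_2A-int under 5 and the others under 8 to 11.

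GSAT_MM had a fitted fold of 0.369 with an adjusted p of 0.0778 in edgeR and was lower in 4 of 4 pairs. TMM and median scaling each called 2 families higher and 0 lower, against 2 higher and 5 lower as deposited, and LINE1 scaling 3 and 1. The count of 7 families was 0 without TKO 2i, and 1 higher and 1 lower without J1 DAXX-knockout regular. MERVL-int and MERVL_2A-int also lost their calls without J1 2i or TKO regular. Their log2 changes of −1.96 and −1.88 were −2.56 and −2.48 without TKO DAXX-knockout regular, and that of MERVL_2A-int was −1.28 without J1 2i. That of MMERGLN-int, 2.18, was 1.59 without J1 DAXX-knockout 2i. GSAT_MM was called without J1 regular, J1 DAXX-knockout 2i or TKO DAXX-knockout regular, and its log2 change of −1.44 was −2.04 without J1 DAXX-knockout 2i. Of single elements 534 were called lower, with 448 of 575 MERVL-int and 63 of 75 MMERVK10C-int among them, and 56 higher, with 48 of 56 MMERGLN-int. Under TMM 62 were higher and 8 lower, under median scaling 362 and 55 and under LINE1 scaling 573 and 65. The count of 590 was reduced, with 17 higher and 1 lower without J1 DAXX-knockout regular, 18 and 11 without TKO 2i, 51 and 5 without J1 2i, 27 and 40 without J1 regular and 51 and 23 without TKO regular. The LINE and LTR types had an adjusted p of 0.999 in camera, and no class by name passed with an estimated correlation, with 0.0692 for MERVL.

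**Figure D3:**
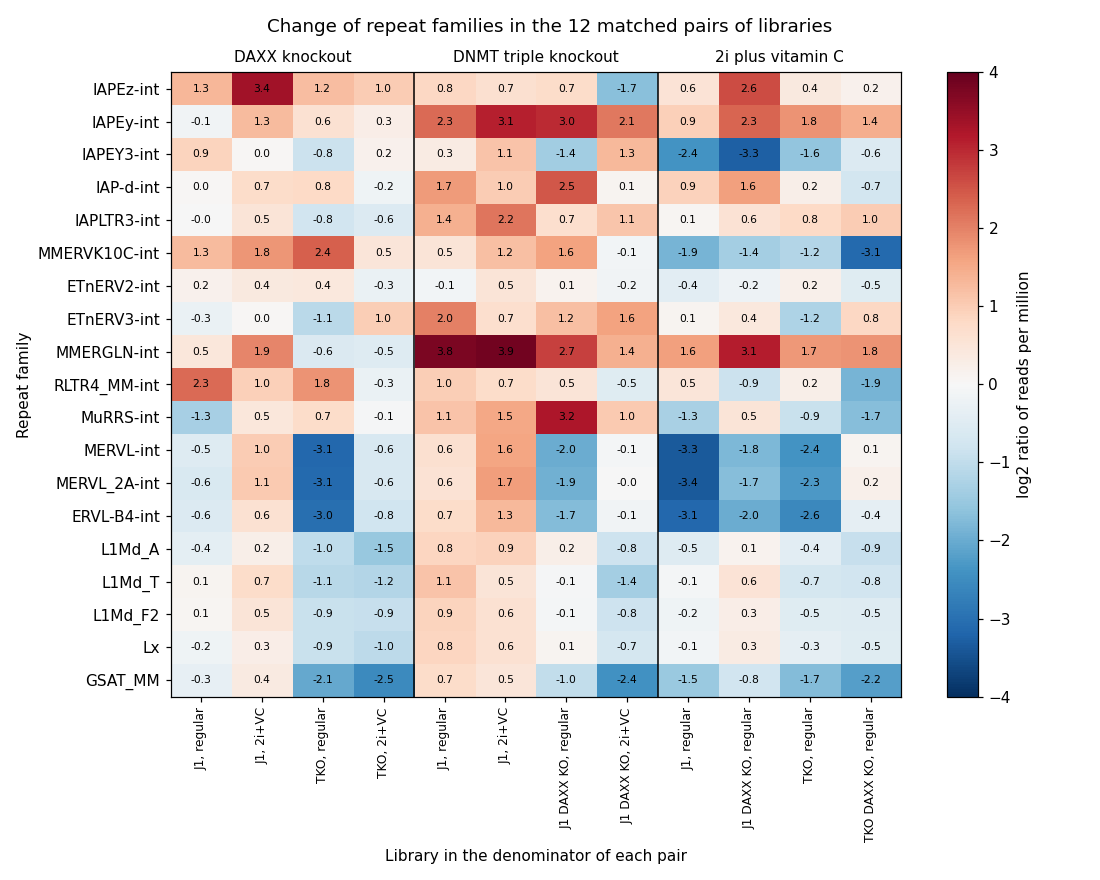
Log2 ratio of RPM for 19 repeat families in the 12 pairs of libraries that differ in 1 factor, with the library of the denominator named under each column. MMERGLN-int was higher in 4 of 4 pairs of TKO over J1, and MERVL-int was lower with 2i plus vitamin C in 3 of 4 pairs.

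No family was called for the interaction of medium with the DNMT background or with DAXX, and 0 had an unadjusted p under 0.05 in edgeR. No element was called for either, with 44 and 14 at an unadjusted p under 0.05.

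Transcripts had been assembled in each library separately, and 9658 loci matched in all 8 libraries were tested with limma. A transcript assembled in only some of the libraries was not tested, so those switched on or off could be missed. For the medium 90 were called higher and 59 lower. The locus on mm9 chromosome 10 from 126952001 to 126954206 rose 8.23-fold with an adjusted p of 0.0231, and that on chromosome 17 from 50418715 to 50433118 rose 6.69-fold with one of 0.0248. The locus on chromosome 18 from 35020645 to 35024639 fell to 0.0957 of its level with an adjusted p of 0.0164, and that on chromosome 15 from 61816933 to 61821846 to 0.105 with one of 0.0416. In the same order these loci lost their calls in 6, 5, 3 and 7 of the 8 omissions of 1 library, with each of the 4 lost without J1 regular, TKO regular or TKO DAXX-knockout 2i. The log2 change of the chromosome 15 locus was −3.25, −2.58 without J1 2i and −3.88 without TKO DAXX-knockout regular. The count of 149 was 0 without TKO regular, 1 without TKO DAXX-knockout 2i, 2 without J1 DAXX-knockout regular, 4 without J1 regular or J1 2i, 14 without TKO 2i, 75 without J1 DAXX-knockout 2i and 444 without TKO DAXX-knockout regular.

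For DAXX limma called 1 locus, on chromosome 4 from 147234908 to 147242736, with a fold of 4.01, a log2 change of 2.00 ± 0.17 (SE) and an adjusted p of 0.0226. Its FPKM was 7.10 in J1 regular, 27.4 in J1 DAXX-knockout regular, 5.13 in TKO regular and 31.7 in TKO DAXX-knockout regular. With any 1 of the 8 libraries left out it did not pass, while its log2 change stayed between 1.89 and 2.06. The nearest listed element was an IAPEz-int copy 20.5 kb away. For TKO against J1 limma called 0 loci, with 1581 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0537, and 1 without TKO regular or TKO 2i. It called 0 within J1 and within TKO, with 559 and 743 at an unadjusted p under 0.05. For the interactions of DAXX with DNMT, medium with DNMT and DAXX with medium it called 0, with 547, 1280 and 248 at an unadjusted p under 0.05, and 1 for medium with DNMT without J1 regular. In single pairs, between 451 and 1599 loci differed at least 2-fold, which carries no test.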

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

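The tests of other splits of the libraries and of elements outside assembled loci were set before their results were seen, and the others in this part were chosen afterwards. The DAXX effect was lower in TKO than in J1 for 57 elements in edgeR's interaction test of the backgrounds. The number called, in either direction, was 0 with TMM, median scaling, LINE1 scaling or a mean RPKM of at least 1, 1 with a limma pseudocount of 1, 2 with limma without trend, 15 with DESeq2 and 171 with no filter. It was 3 without J1 regular or J1 2i, 6 without TKO regular, 11 without TKO 2i, 344 without J1 DAXX-knockout 2i, 455 without TKO DAXX-knockout regular, 611 without TKO DAXX-knockout 2i and 9092 without J1 DAXX-knockout regular. The number of loci assembled over IAPEz-int elements in a library, a count that enters no test, was 70 in J1 DAXX-knockout regular against 65 in J1 regular, and 73 in J1 DAXX-knockout 2i against 68 in J1 2i. In TKO it was 74 against 69 in regular medium and 76 against 69 in 2i.

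Relative to library totals, LINE1 reads were lower in the DAXX-knockout TKO libraries, with the median L1 family at log2 −1.05 over the TKO pairs, but this rests partly on high intact TKO libraries, since LINE1 elements were at 149042 and 100179 RPM in TKO, 71687 and 40717 with DAXX knockout and between 62308 and 91763 in the 4 J1 libraries. A single factor per library as the whole cause would move LTR families by as much. It is argued against by their median of 0.14 (quartiles −0.48 and 0.41). This alone does not show whether LINE1 fell or LTR families rose, nor exclude a factor as part of the cause. The median of the 9658 assembled loci changed with DAXX knockout by log2 0.08 in TKO regular and 0.004 in TKO 2i. If FPKM and RPM share a scale, which the sources do not state, LINE1 was lower relative to these loci. Transcripts running through elements cannot be told apart: L1Md elements outside assembled loci had a median of −1.09 beside −1.03 inside, but reads shared between near-identical copies would make both move alike, so the bound set beforehand does not hold. Background reads unrelated to element age remain a candidate explanation, since the median of the 15 older L1 families was −1.09 beside −1.14 for the 6 L1Md families, although the test first used L1VL2 and L1VL4, at 0.10 and −0.50 with 1551 and 1295 reads, which pointed against background, and was widened to all older families after those values had been seen. A difference between the lines other than DAXX cannot be told apart, with 1 library of each line in each medium, and an effect of losing DAXX stays open, with adjusted p of 0.0747 for L1Md_A and 0.0764 for L1Md_T in TKO in edgeR.

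IAPEz-int reads were highest in J1 DAXX-knockout 2i, at log2 3.37 over J1 2i. Library scaling is argued against by the other 43 families, whose median was 0.50 in that pair. A few elements taking the reads cannot be told apart, because 99.8% of IAPEz-int elements were at least 2-fold higher but reads shared between copies would give this too. A difference between single cultures cannot be told apart, with 1 library of this line in this medium, and an effect of losing DAXX stays open, with an adjusted p of 0.179 in J1 in edgeR.

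Each factor was compared with other splits of the 8 libraries into 4 and 4, of which 33 could be fitted, the real split included. Some of the 33 differ only by the covariates and are the same fit. For the DNMT background the 2 splits with 6904 elements and 5 families called are 1 fit, counted 2 times below. For elements, 2, 5 and 4 of the 33 gave as many calls as DAXX, DNMT background and medium (real 766, 69 and 590, highest other 8651, 6904 and 7098). Other splits can hold part of the tested factor or interactions, so they are no measure of chance. The split with 8651 calls sets the DAXX-knockout TKO libraries against the intact TKO libraries. Whether chance gives as many calls was therefore not decided. Why other splits called 8651 elements for DAXX, 6904 for the DNMT background and 7098 for the medium was not tested. For families, 3 and 2 gave as many as DNMT background and medium (real 5 and 7, highest other 5 and 17). For loci 4 gave as many as DAXX (real 1, highest other 1). For the same reason these counts do not decide about chance. For the medium 1 split, the real one, gave as many as its 149 loci, with 2 as the highest other. This is the lowest rank that 33 splits can give, which by itself does not exclude chance, and the count was 0 without TKO regular. The remaining counts say nothing about chance either. A real count of 0 is reached by any split, as by all 33 for DAXX families (highest other 24), DNMT loci (highest other 1) and medium sets (highest other 2). For the LINE and LTR sets under DAXX and DNMT, 33 and 31 splits gave the 2 sets, which is as many as there are (highest other 2).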

How the results depend on the processing

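TMM, DESeq2, LINE1 scaling, 80% overlap, the test of classes by name and every family count were chosen after seeing the data. Of counts, 239 were equal or stayed within 1.5 times and 123 moved. The 239 include many counts of 0 that stayed at 0, such as those of loci for DAXX by DNMT, which show no calls that held. Of named values 618 kept direction and side of the threshold, 60 became called, 171 lost the call and 3 reversed. With 4 residual degrees of freedom small changes could be missed, and the simulation does not give the share missed in these data. The cause of each change below was not tested.

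Omitting 1 library gave, for loci, 0 to 1 for DAXX, 0 to 1 for DNMT, 0 to 444 for the medium and 0 to 1 for medium by DNMT. For elements it gave 0 to 4252 for DAXX, 45 to 118 for DNMT, 18 to 801 for the medium, 0 to 2997 in J1, 3 to 10131 in TKO and 3 to 9092 for DAXX by DNMT. For families the ranges were 0 to 3, 2 to 7, 0 to 9, 0 to 3, 0 to 24 and 0 to 24 in that order. For LINE and LTR sets they were 0 to 2 for DNMT and 0 to 2 for the medium.

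For loci, all 2-way interactions gave 0 for DAXX and 227 for the medium, 80% overlap 0 for DAXX, median scaling 4 for DNMT and no covariates 97 for the medium. For elements, DNMT gave 351 with median scaling, 327 with TMM and 348 with LINE1 scaling, the medium 70 with TMM and J1 503 with TMM. In TKO there were 1555 with no filter, 2 at a mean RPKM of at least 1, 869 with median scaling, 817 with TMM and 934 with LINE1 scaling. DAXX by DNMT gave 1 with a limma pseudocount of 1, 2 with limma without trend, 171 with no filter, 15 with DESeq2 and 0 at a mean RPKM of at least 1, median scaling, TMM or LINE1 scaling.

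For families, DAXX gave 1 with TMM, median scaling, LINE1 scaling or DESeq2, DNMT 3 with LINE1 scaling and 9 with DESeq2, and the medium 2 with TMM, 2 with median scaling and 4 with LINE1 scaling. J1 gave 1 with DESeq2, TKO 0 with TMM, 9 with LINE1 scaling and 25 with DESeq2, and DAXX by DNMT 23 with DESeq2. With an estimated correlation the sets fell to 0 for DAXX and 0 for DNMT, and classes by name to 1, 1 and 0 for DAXX, DNMT and medium. LINE1 scaling, which sets L1Md_T near 0 by its own construction, gave it log2 0.11 for DAXX and 0.043 in TKO, and reversed IAPEz-int to 0.14 for DAXX by DNMT. Gene lists and the choice among entries of a gene were not run, since the loci carry no names.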

Other observations

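The test of all loci near IAPEz-int elements was set before its result was seen, and the test without overlapping loci was chosen afterwards. ETnERV2-int and MMETn-int, both of the ERVK type, were among the abundant LTR families, at 8853 to 14692 RPM and 8225 to 12796 RPM over the 8 libraries. With DAXX knockout their fitted folds were 1.14 and 1.17, with adjusted p of 0.673 and 0.673 in edgeR.

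The hypothesis was that assembled loci within 10 kb of an IAPEz-int element rise with DAXX knockout. The 92 such loci had a median log2 change of 0.08, at percentile 99.7 of 10000 random lists matched on mean FPKM. The 49 that overlapped an element had a median of 0.08, at percentile 98.1, and the 43 that did not had one of 0.05, at percentile 92.2. Whether these parts differ was not tested. The percentiles describe these libraries.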
